A study of Homo sapiens with 6 samples.

How the data were processed

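Total RNA was extracted with Trizol and sequencing libraries were made with a stranded total RNA kit, per the labels' protocols. The labels describe 6 samples of HCT116 cells, 3 given DMSO and 3 given 1 µM BMH-21 for 6 h, and these were the 2 groups compared. Gene expression was deposited as FPKM (fragments scaled by transcript length and library size). TopHat2, Cuffdiff 2.0 and the genome build GRCh37 are named in the submitters' processing notes, with no order or settings. The annotation, the filters and the pooling of samples by the authors are not given in the sources used here.

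The deposited table has 25548 gene symbols and 3 columns per group, named as replicates 1, 2 and 3. These columns were checked before any comparison was computed. In the control, the first column was the midpoint of the other columns, within a relative tolerance of 0.0001, in 15411 of the 15418 genes with a second column above 0. After BMH-21 this held for 15521 of 15529 genes. The second column was at or below the first, and the third at or above it, in 99.95% of control and 99.94% of BMH-21 genes with an estimate above 0. Independent libraries would not give this pattern, which is that of an estimate with symmetric confidence limits, as Cuffdiff writes them. The first column was therefore used as the deposited FPKM estimate of the group, and the other columns as its deposited lower and upper limits on the FPKM scale, a reading taken from the values. How many libraries entered each estimate, how the limits were computed and the sequencing depth cannot be read from the table. The precision is that of the limits, whose median half-width was 17.3% and 17.4% of the estimate in 8434 control and 8336 BMH-21 genes at 5 FPKM or more. The 5th percentile was 16.8% in both groups, and the 95th percentile was 30.4% in the control and 31.5% after BMH-21. Many genes thus had limits of nearly the same relative width, and for them limits that do not overlap come close to a fixed ratio of the estimates.

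The design fixed before the data were examined was a limma model of log2(FPKM + 1) on 6 samples with camera tests of gene lists. It could not be run as a test of replicates, because the table holds no replicate values. It was replaced, after the content of the columns was seen and before any group comparison was computed, by the following rules. Genes were kept with a mean of the group estimates of at least 1 FPKM, which left 12151 genes. This count excludes 7 genes above the minimum, of 12 in all, whose estimate lay outside its own limits. A gene was called higher or lower after BMH-21 where the limits of the groups did not overlap. The log2 change is log2(FPKM + 1) after BMH-21 minus that in the control, which understates the change of low genes, and folds given as such are ratios of the FPKM estimates. No p-value enters these calls, and those computed in alternatives are not p-values across replicates.

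The 35 gene lists were fixed before the data were examined, from textbook knowledge. For the 32 lists with at least 5 kept members, the median log2 change was placed as a percentile among 10000 random lists of the same size, drawn from kept genes in 20 strata of mean FPKM. A list was called outside its range below percentile 2.5 or above percentile 97.5, which describes these estimates and is not a test across replicates. Of the 32 lists, 8 lay above and 7 below, where random draws of genes would give 1.6. Random draws ignore that members of a list can move together, so 1.6 does not state how many such lists would lie outside without BMH-21. Some genes belong to more than 1 list. The genes named in the text follow a rule fixed beforehand. It takes the 15 largest rises and the 15 largest falls among called genes with at least 5 FPKM in the higher group, without small RNA genes, and up to 4 members per list. It also takes POLR1A, TP53, CDKN1A, MDM2, MYC, UBTF and RRN3. The 4 members with the lowest p-values had been planned and were replaced by the 4 with the largest difference of the estimates relative to the summed half-widths of the limits. Small RNA genes were recognised by the start of the symbol, such as MIR followed by a digit, and 315 genes recognised in this way were kept. This missed the microRNA genes MIRLET7I and MIRLET7D, which so remain among the 15 largest rises and in the counts without small RNA genes, and it took in the long host transcripts MIR17HG and MIR22HG.

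Transcript GC, gene length and gene order came from GENCODE release 29 and NCBI RefSeq, both on GRCh38. Since the notes name GRCh37, no coordinates are given. Of the symbols, 18232 matched by current symbol and 1604 by an older one, and 91.4% of kept genes had a transcript GC. The correlation of log2 changes between neighbouring, non-overlapping genes was computed on differences from the median of genes matched on GC, expression and length, limited to 1.5 in size, and set beside 1000 reorderings within matched genes.

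The rules were tested on simulated data for the 12151 genes of this comparison, with limits taken as 2 SD from the estimate. Of 67 genes changed by each fold, 61.2% were recovered at 1.5-fold, 91.0% at 2-fold and 95.5% at 4-fold. Of the unchanged genes 0.762% were called. Of random lists, 4.5% lay outside the central 95%. The simulated noise had the same relative SD that set the limits, and genes were drawn independently. How the deposited limits were computed is unknown, so these rates are not error rates of the calls made here. The alternatives were other pseudocounts (0.1 and 0.5), no filter or a filter at 5 FPKM, a 1.5-fold size limit, scaling by the median log ratio, quantile normalization, and rescaling to a common total without small RNA genes. Small RNA genes left out without rescaling, other calling rules, the limma model with the 3 columns entered as replicates, and random lists also matched on GC were added after the data were seen. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.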

Results

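RNA sequencing was used to compare gene expression in HCT116 cells with and without BMH-21. HCT116 is a human colorectal carcinoma cell line, here with both copies of TP53 intact, so that the tumour suppressor p53 is made. BMH-21 is a small molecule inhibitor of RNA polymerase I, the enzyme that transcribes the ribosomal RNA genes. The labels name 6 samples, with 3 control samples given DMSO and titled 0 h, and 3 samples given 1 µM BMH-21 for 6 h. No control titled 6 h is named, so effects of time or handling cannot be told apart from those of BMH-21. The comparison asked how the transcriptome of these p53-proficient cells changed after 6 h of the inhibitor. The deposited table listed 25548 genes with 3 columns per group named as replicates. In 99.95% of genes with a second column above 0, the first column was the midpoint of the other two, in both groups. The columns were therefore read as 1 FPKM estimate per group with a lower and an upper limit, all of them the authors' values. No replicate values could be read from the table, so the difference has no replicate check, and no SD or p-value is given. Sequencing depth is unknown. FPKM summed to 750294 in the control and 788881 after BMH-21. Among genes at 5 FPKM or more, the median half-width of the limits was 17.3% of the estimate in the control and 17.4% after BMH-21. The 5th percentile was 16.8% in both groups, so many genes had limits of nearly the same relative width.

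After BMH-21 a minority of genes differed from the control, and the genes with the largest rises, small RNA genes left aside, were mostly known targets of p53. CDKN1A, which encodes the cell cycle inhibitor p21, rose from 45.6 FPKM (limits 37.9 to 53.3) to 472 FPKM (limits 373 to 571). The largest falls included SLC19A1, a folate transporter, which fell from 34.7 FPKM (limits 28.8 to 40.6) to 2.98 FPKM (limits 2.30 to 3.66). A gene was called higher or lower where the limits of the 2 groups did not overlap, and rose and fell are used only of such genes. Of 12151 genes with a mean of at least 1 FPKM, 733 were higher and 1110 were lower after BMH-21, which is 15.2% of the genes. A change of at least 2-fold on the log2(FPKM + 1) scale was found for 138 of the higher and 227 of the lower genes. The median log2 change was 0.02, and the central 90% of genes lay between −0.67 and 0.53. Without small RNA genes, whose estimates in this kind of library are often listed at 0, the counts with at least 2-fold change were 83 higher and 190 lower. When the remaining genes were also rescaled to a common total, 483 genes were higher and 1340 lower, so that 26.5% of the called genes were higher, compared with 38.7% before rescaling and 39.8% with small RNA genes included.

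**Figure D1:**
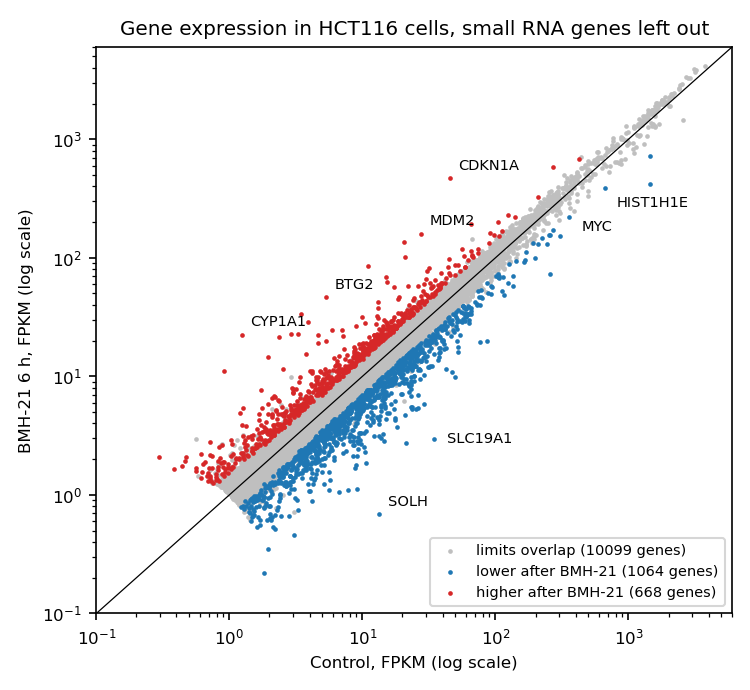
FPKM of each gene in the control (x axis, log scale) and after 6 h of BMH-21 (y axis, log scale), small RNA genes left out; each point is 1 gene, colours mark genes whose deposited limits did not overlap, and the line marks equal values. Of the 11831 genes drawn, 668 were higher and 1064 lower, and 5 kept genes listed at 0 in one group are not drawn.

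Most measured targets of p53 rose. Of 48 members of the list, 36 were higher, 1 was lower and 11 had overlapping limits. The median log2 change of the list was 1.10, above all 10000 random lists of the same size matched on mean FPKM (percentile 100), whose central 95% lay between −0.07 and 0.14. MDM2, the ubiquitin ligase that degrades p53, rose from 27.7 FPKM (limits 22.9 to 32.6) to 160.2 FPKM (limits 124 to 197). The antiproliferative gene BTG2 rose from 5.35 FPKM (limits 4.35 to 6.34) to 46.7 FPKM (limits 38.8 to 54.7). SESN1 and SESN2, which encode stress-induced sestrins, rose 7.39-fold and 9.04-fold, and the secreted factor GDF15 rose 7.72-fold. Among genes of cell death, BBC3, which encodes PUMA, rose from 2.93 FPKM (limits 2.25 to 3.60) to 22.8 FPKM (limits 18.9 to 26.7), the death receptor gene FAS rose 7.02-fold and TP53INP1 rose 7.35-fold. The decoy receptor gene TNFRSF10C, which was not in the list, rose 12.2-fold from 0.905 FPKM (limits 0.633 to 1.18), to limits of 8.99 to 13.0 FPKM. The member that fell was NINJ1, from 15.7 to 10.9 FPKM. BAX was at 37.3 FPKM in the control (limits 30.7 to 43.9) and 48.3 FPKM after BMH-21 (limits 39.9 to 56.7), and these limits overlapped. NINJ1 and BAX were picked after their values were seen. TP53 itself was at 19.8 FPKM (limits 15.6 to 24.0) and 22.7 FPKM (limits 18.0 to 27.3), also with overlapping limits.

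**Figure D2:**
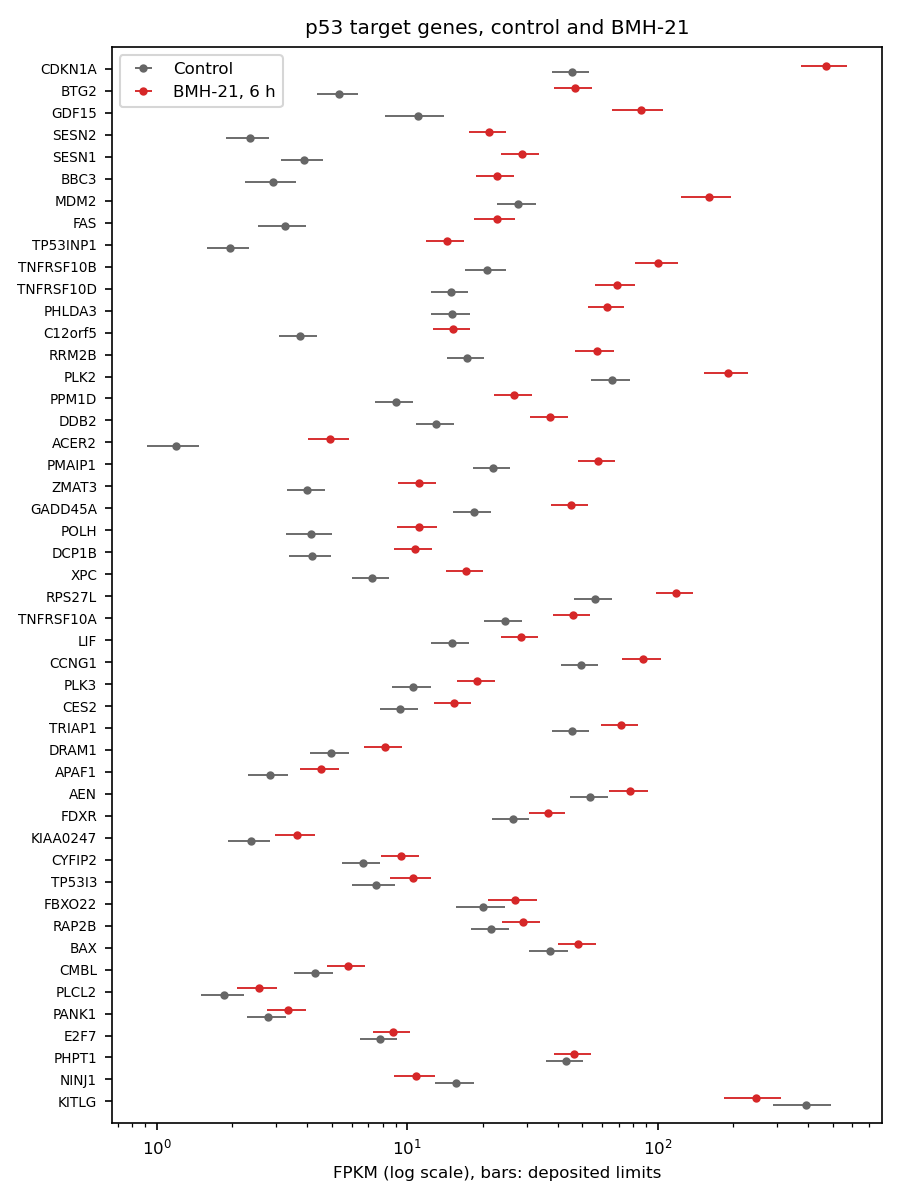
FPKM (log scale) of the 48 measured p53 target genes in the control (grey) and after 6 h of BMH-21 (red); points are the deposited estimates and bars the deposited limits. CDKN1A rose from 45.6 to 472 FPKM, and 36 of the 48 genes were higher with limits apart.

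Outside the p53 list, the 15 largest rises selected held CYP1A1, ATF3, TNFRSF10C and LOC100653010. CYP1A1, a cytochrome P450 enzyme of xenobiotic metabolism, rose from 1.24 FPKM (limits 0.952 to 1.53) to 22.4 FPKM (limits 18.6 to 26.2). LOC100653010, an uncharacterised locus, rose 6.66-fold to 137 FPKM. The let-7 microRNA genes MIRLET7I and MIRLET7D were also selected, because the symbols used to leave out small RNA genes missed them. They were listed at 0 in the control, which can be a failed estimate, and at 37.4 and 29.5 FPKM after BMH-21, so that their calls are uncertain. The immediate early genes, which respond first to growth and stress signals, lay above their random range as a group, with 17 of 32 members higher and 3 lower and a median log2 change of 0.62 (percentile 100). ATF3, a stress-induced transcription factor, rose from 3.47 FPKM (limits 2.76 to 4.17) to 33.7 FPKM (limits 27.9 to 39.4). PPP1R15A, a phosphatase regulator of the stress response, rose 3.07-fold, and BTG1 and CTGF had log2 changes of 1.10 and 1.06. The members that fell were MYC, JUND and ZFP36L2, the last 2 named after their values were seen. MYC, a transcription factor of cell growth, fell from 359 FPKM (limits 284 to 434) to 221 FPKM (limits 179 to 263), a log2 change of −0.70. It was the called member among the 8 measured genes of MYC and its partners, and that list lay within the random range (percentile 28.8).

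Most measured genes of the G1/S transition and DNA replication fell. Of 36 measured members, 22 fell, none rose, and the median log2 change was −0.72 (percentile 0). CHAF1A, a subunit of the chromatin assembly factor that deposits histones at replication forks, fell from 25.2 FPKM (limits 20.9 to 29.5) to 5.33 FPKM (limits 4.38 to 6.27). The replication licensing factor CDT1 fell from 42.7 FPKM (limits 35.4 to 49.95) to 11.5 FPKM (limits 9.53 to 13.5). The transcription factor genes E2F1 and E2F2 had log2 changes of −1.20 and −1.38. Genes of DNA repair lay below their random range as a group, with 13 of 40 members lower and 1 higher and a median log2 change of −0.19 (percentile 0.11). XRCC3, XRCC2 and RAD51 of homologous recombination had log2 changes of −1.97, −1.37 and −1.01, and the member that rose was ERCC4, named after its values were seen, at a log2 change of 0.49. Genes of G2 and mitosis had a median log2 change of −0.10 (percentile 0.30), but AURKB, a mitotic kinase, was the 1 member of 40 that passed. Its value fell from 33.2 FPKM (limits 27.5 to 38.9) to 21.3 FPKM (limits 17.5 to 25.03). Replication-dependent histone genes had a median log2 change of −0.18 (percentile 0), with 5 of 48 members lower and 4 higher. The linker histone gene HIST1H1E fell from 1458 FPKM (limits 1147 to 1768) to 420.3 FPKM (limits 346 to 494), whereas HIST1H2BL rose from 124 FPKM (limits 103 to 145) to 229 FPKM (limits 189 to 269). The other lower members were HIST3H2BB, HIST2H2BF, HIST1H2AK and HIST1H4K, and the other higher ones HIST1H2BG, HIST1H2AE and HIST1H2BB, of which HIST3H2BB and HIST1H2BG came from the rule for named genes and the rest were named after their values were seen. Histone genes have close copies whose reads the authors' counting could split, so values of single members are uncertain.

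At the RNA level, genes of the machinery that BMH-21 acts on were called about as often as genes at large. Of 15 genes of the RNA polymerase I machinery, 2 fell and none rose, where 15.2% of all kept genes were called. The list lay within the random range (median log2 change −0.06, percentile 12.2). UBTF, which binds the ribosomal DNA promoter, fell from 37.3 FPKM (limits 30.7 to 43.9) to 15.7 FPKM (limits 13.1 to 18.4). POLR1E fell from 56.9 FPKM (limits 47.1 to 66.6) to 39.1 FPKM (limits 32.4 to 45.7). The largest subunit gene, POLR1A, was at 13.3 FPKM (limits 11.02 to 15.6) and 11.4 FPKM (limits 9.47 to 13.3), and the initiation factor gene RRN3 was at 41.9 FPKM (limits 34.6 to 49.2) and 47.8 FPKM (limits 39.5 to 56.2), both with overlapping limits. Among 22 genes of the RNA polymerase III machinery BRF1, POLR3K and POLR3H fell, with log2 changes of −1.68, −0.95 and −0.97 (list percentile 12.2). Of 12 RNA polymerase II subunit genes, POLR2A alone was called, at a log2 change of 0.49 (list percentile 77.9), and its limits overlapped after rescaling without small RNA genes. Ribosome assembly factors had a median log2 change of −0.05, below nearly all random lists (percentile 0.030), with 4 of 70 members lower and 1 higher. BOP1 fell from 112 FPKM (limits 92.2 to 132) to 52.2 FPKM (limits 43.3 to 61.1), NLE1 and MYBBP1A had log2 changes of −0.83 and −0.64, IMP3, named after its values were seen, fell by 0.53 on the log2 scale, and UTP3 rose by 0.58. Of the 77 cytosolic ribosomal protein genes, 73 had log2 changes above 0. Their median was 0.19, within the range of equally abundant genes (percentile 82.5), but the random lists could draw these same genes. The 1 called member of the list, RPS17, was listed at 0 in the control and at 2.34 FPKM after BMH-21. This level is far below that of RPS27 at 3114 and 3925 FPKM, and the near-identical copy RPS17L makes the call of RPS17 uncertain. Of 75 mitochondrial ribosomal protein genes, MRPL12 and MRPL34 fell and MRPS9 rose (percentile 24.8), the last losing its call under each of 3 other scalings. Of 15 snoRNA host genes SNHG7 fell, at a log2 change of −1.26 (percentile 6.6).

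**Figure D3:**
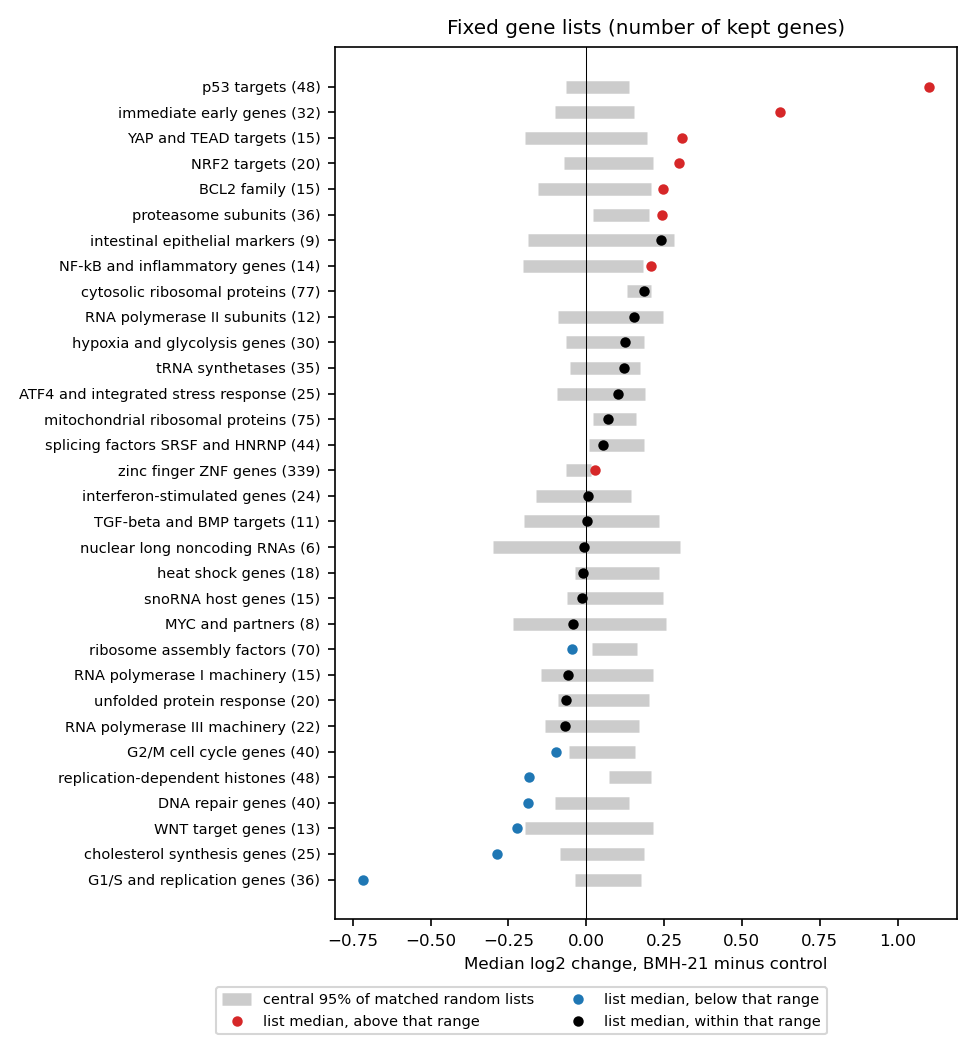
Median log2 change (BMH-21 minus control, x axis) of the 32 gene lists with enough measured members; points are list medians and grey bars the central 95% of 10000 random lists of the same size matched on mean FPKM. The p53 targets lie at 1.10 and the G1/S genes at −0.72. Outside their range lie 15 lists, where random draws of unrelated genes would give 1.6.

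Further lists of stress and signalling genes lay above their random range. NRF2 targets, of the oxidative stress response, had a median log2 change of 0.30 (percentile 99.97), with SLC7A11, GCLM and OSGIN1 higher and HMOX1 lower among 20 members. Targets of YAP and TEAD had a median of 0.31 (percentile 99.92), with 6 of 15 members higher, among them NT5E and the immediate early genes CTGF and CYR61, and with FJX1 lower at a log2 change of −1.77. The BCL2 family of cell death regulators had a median of 0.25 (percentile 99.4), with BBC3 and PMAIP1, both also p53 targets, and BIK higher. The family was split, with 8 log2 changes above 0 and 7 below. Its median was the smallest of the 8, that of BCL2L12, and the next value was BCL2L11 at −0.12. BOK fell from 20.9 FPKM (limits 17.3 to 24.5) to 4.71 FPKM (limits 3.83 to 5.60) and was the 1 lower member of 15. NF-kB and inflammatory genes had a median of 0.21 (percentile 98.6), with IL8, NFKB2 and LIF, also a p53 target, higher among 14 members. The other 11 had overlapping limits, and IL8 was low, at 0.460 FPKM in the control and 1.95 FPKM after BMH-21. Proteasome subunit genes had a median of 0.24 (percentile 99.8), but none of the 36 members passed on its own. PSMB3, for example, was at 248 FPKM (limits 205 to 291) and 332 FPKM (limits 273 to 391). The 339 ZNF zinc finger genes had a median of 0.03 (percentile 99.6) with 19 higher and 34 lower. That list fell within the range (percentile 85.3) when random lists were also matched on transcript GC. Its median was −0.04 after rescaling without small RNA genes, where the median of all genes compared was −0.05. The BCL2, NF-kB and ZNF lists lost their calls with no filter on low values, and the NF-kB list also with a filter at 5 FPKM.

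Cholesterol synthesis genes and WNT targets lay below their random range. The cholesterol list had a median log2 change of −0.29 (percentile 0) with 5 of 25 members lower and none higher. INSIG1, a sterol sensor, fell from 76.9 FPKM (limits 63.2 to 90.5) to 39.9 FPKM (limits 33.0 to 46.9), and the enzyme genes DHCR7, MVD and MVK had log2 changes of −0.84, −0.74 and −0.62. The remaining lower member, PCSK9, was named after its values were seen, at a log2 change of −0.48. WNT targets had a median of −0.22 (percentile 1.6), a call lost with a filter at 5 FPKM, and CCND1, EPHB2, RUNX3 and NKD1 fell among 13 members, NKD1 without a call after quantile normalization. CCND1, which encodes cyclin D1, fell from 243 FPKM (limits 191 to 295) to 131 FPKM (limits 106 to 157).

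The remaining lists lay within their random range. The integrated stress response list split, with 6 of 25 members higher, including SESN2, ATF3 and PPP1R15A, and 4 lower (percentile 73.3). The lower members were ATF4, CEBPG, SLC7A1 and TRIB3, named after their values were seen, and ATF4, the transcription factor after which the list is named, fell by 0.78 on the log2 scale. Among 20 genes of the unfolded protein response SDF2L1, DNAJB9 and HERPUD1 fell (percentile 4.7). Among 18 heat shock genes DNAJB1 fell and HSPA4L rose (percentile 5.0), and this list lay below the range (percentile 2.1) when random lists were also matched on GC. Matching on GC also placed the median of the cytosolic ribosomal proteins, 0.186, at the upper limit of the range, also 0.186 (percentile 97.54). Random lists could draw members of the list itself. Of 44 splicing factor genes HNRNPR, SRSF3, SRSF4 and SRSF6 fell, SRSF6 named after its values were seen, and SRSF8 rose (percentile 13.7). Of 11 TGF-beta and BMP targets SKI, ID3 and ID1 fell and SKIL rose (percentile 38.4). Of 30 hypoxia and glycolysis genes PFKFB4 and HK2 fell and KDM3A and P4HA1 rose (percentile 76.7), of 24 interferon-stimulated genes PARP14 rose (percentile 56.1), and KDM3A, P4HA1 and PARP14 lost their calls after rescaling without small RNA genes. Of 35 tRNA synthetase genes HARS2 fell (percentile 83.4), and of 6 nuclear long noncoding RNAs MIR22HG rose and MIR17HG fell (percentile 39.3), the latter without a call after quantile normalization. Of 9 intestinal epithelial markers KRT20 and ELF3 rose and KRT18 fell from 1458 FPKM (limits 1051 to 1865) to 725 FPKM (limits 563 to 888), with a list percentile of 93.1. Markers of other cell types were nearly absent. Of 21 blood cell markers in the table only CD68 reached the minimum, at 1.78 and 1.30 FPKM with overlapping limits, and of 21 fibroblast and endothelial markers only ACTA2, which rose from 1.27 FPKM (limits 0.663 to 1.88) to 5.45 FPKM (limits 2.52 to 8.39). ACTA2 overlaps FAS on the opposite strand in the annotation used. No mitochondrially encoded mRNA was found under the symbols searched.

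Small RNA genes left aside, the genes with the largest falls were mostly outside the lists. SLC19A1 and SOLH had the largest falls, and their order depended on the pseudocount. SOLH fell from 13.4 FPKM (limits 11.1 to 15.7) to 0.685 FPKM (limits 0.501 to 0.869), and TIGD5 fell from 21.2 FPKM (limits 17.6 to 24.8) to 2.71 FPKM (limits 2.12 to 3.31). KIF26A, FAM83H, BAIAP2, C8orf55, RPUSD1, FAM20C, C14orf80, LOC100652746, NACC2 and KCTD5 followed with log2 changes between −2.24 and −2.01. The listed genes CHAF1A and XRCC3 completed the 15 largest falls, at −2.05 and −1.97. The genes that fell had GC-rich transcripts, with a median GC of 57.2% compared with 44.8% in the genes that rose and 48.4% in those with overlapping limits. In the decile of genes with the highest transcript GC, 24.955% were lower and 2.43% higher, and the median log2 change was −0.21. In the lowest decile, 3.24% were lower and 9.99% higher, and the median log2 change was 0.14. Across genes, which are not independent replicates, the log2 change correlated with transcript GC at a Spearman rho of −0.29 and with gene length at 0.016. Apart from the ZNF list, each of the lists outside its range stayed outside it when random lists were also matched on GC.

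**Figure D4:**
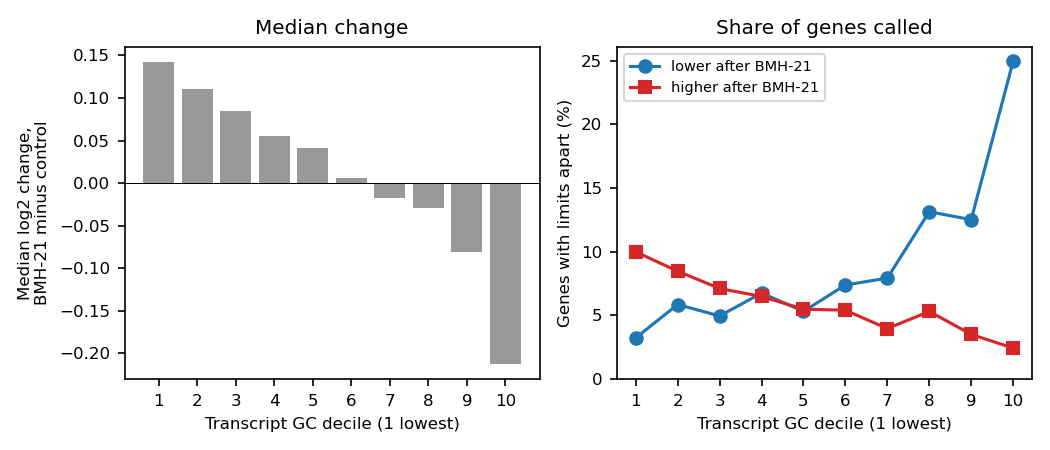
Left, median log2 change (BMH-21 minus control) of genes in each decile of transcript GC, from the lowest (1) to the highest (10); right, percent of genes in each decile called lower (blue) or higher (red). The share called lower goes from 3.24% in the lowest decile to 24.955% in the highest, and the share called higher from 9.99% to 2.43%.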

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

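No paired analysis was possible because the columns named as replicates hold 1 estimate and its limits, so no column holds the values of 1 replicate. For the same reason the planned fits without each replicate, without the trend or with the robust option, and the list tests with an estimated correlation or by fry, were not run. The calling rules other than non-overlapping limits, leaving out small RNA genes without rescaling, the limma model on the 3 columns and matching on GC were chosen after the data were seen. Under the alternatives that recomputed named genes, none changed direction. Counted over genes and alternatives, the call was kept or stayed absent in 1407 cases, was gained in 56 and was lost in 12. Many of these cases were fixed in advance. Other pseudocounts, the filters and leaving out small RNA genes without rescaling could not change the call or direction of a kept gene. Requiring only that each estimate lie outside the limits of the other group could not lose a call. The other calling rules used the same log2 changes, so they could not change a direction. Of 1843 called genes, 1784 were shared after scaling by the median log ratio, 1725 after quantile normalization and 1548 after rescaling without small RNA genes. A filter at 5 FPKM left 1208 called genes, 710 of them lower, because fewer genes were kept. Rescaling without small RNA genes gave 483 higher, 90 of them by 2-fold, and leaving those genes out without rescaling gave 83 higher by 2-fold. A pseudocount of 0.1 gave 342 lower by 2-fold, since it shrinks low genes less, and a size limit of 1.5-fold gave 420 higher and 719 lower. Requiring only that each estimate lie outside the limits of the other group gave 4527 called genes, 2161 higher and 2366 lower. Log ratios with limits taken as 2 SD gave 85 higher by 2-fold, since genes listed at 0 have no ratio. Entering the 3 columns as replicates in limma called 530 genes (adjusted p under 0.05), 181 higher and 349 lower, all 530 shared with the 1843, and 1778 genes at an unadjusted p under 0.05, but these are not p-values across replicates. The lists called numbered between 12 and 16. With no filter, list medians changed sign for MYC and partners (0.067), heat shock genes (0.0044) and interferon-stimulated genes (−0.013). With the filter at 5 FPKM they did for the same lists (0.067, 0.019 and −0.021). After scaling by the median log ratio they did for TGF-beta targets (−0.018) and interferon-stimulated genes (−0.012), and after quantile normalization for TGF-beta targets (−0.020) and splicing factors (−0.041). After rescaling without small RNA genes they did for TGF-beta targets (−0.073), interferon-stimulated genes (−0.063), mitochondrial ribosomal proteins (−0.0033), splicing factors (−0.022) and ZNF genes (−0.037). Rescaling multiplied each group by 1 factor. The median log2 change of all genes compared moved from 0.017, with small RNA genes left out, to −0.054. Scaling by the median log ratio moved it from 0.020 to 0.00094. Such a common shift can turn list medians near 0 negative and lower the count of higher genes. The causes of the other sign changes and of the lower counts in limma were not tested. Apart from ZNF, none of the lists that changed sign was outside the range of random lists matched on mean FPKM alone in the main setting. Heat shock genes were below it with GC also matched. Depth is unknown, so what it limits cannot be stated.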

Other observations

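The values of CYP1A1 led to a look at other targets of the aryl hydrocarbon receptor, a sensor of planar aromatic compounds, so this list was chosen after the result was seen. CYP1B1 rose from 1.72 FPKM (limits 1.38 to 2.06) to 7.64 FPKM (limits 6.33 to 8.94), and TIPARP from 44.5 FPKM (limits 36.7 to 52.2) to 96.9 FPKM (limits 78.8 to 115). AHRR, NQO1 and ALDH1A3 had overlapping limits, with log2 changes of 0.07, 0.34 and 0.0022. CYP1A2 was near 0 in both groups.

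Variant histone genes, also listed after the data were seen, did not move together. H2AFX, which marks DNA breaks when phosphorylated, fell from 255 FPKM (limits 210.0 to 300) to 73.0 FPKM (limits 60.9 to 85.0), and H1FX fell from 47.5 FPKM (limits 39.3 to 55.6) to 27.6 FPKM (limits 22.8 to 32.4). H2AFZ, H2AFV, H2AFJ, H2AFY, H3F3A, H3F3B and H1F0 had overlapping limits, with log2 changes between 0.13 and 0.68.

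Of the patterns weighed next, the tests of the replicate columns and of MIR3648 were chosen only after the result was seen, and those on GC-rich transcripts before. The first pattern is the content of the columns named as replicates. If they held 3 independent replicates, the first column would rarely be the midpoint of the others, but it was in 99.9485% or more of the genes with a second column above 0 in each group. This argues against replicate values and is consistent with a pooled estimate and its limits, a reading that no label states. No biological explanation was tested.

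The second pattern is that genes with GC-rich transcripts were lower after BMH-21. GC bias of the libraries would move genes of equal GC together. The interquartile range of log2 changes in the highest GC decile was 1.38 times that of the 5th and 6th deciles. This lies between the bounds set beforehand for and against such bias, so bias cannot be told apart from an effect of BMH-21. The highest decile also spans 62.3% to 74.4% GC, and the 5th and 6th together 46.0% to 52.3%. Bias alone could therefore widen the highest decile, and the ratio does not count against it. After matching on GC, expression and gene length, log2 changes of 9511 pairs of neighbouring genes still correlated at 0.10 across genes, above the highest of 1000 reorderings (0.035). Without matching, 18.1% of the genes following a gene called lower were lower, compared with 8.70% elsewhere, a contrast that includes GC shared by neighbours. A candidate explanation is an effect of the drug shared by regions of the genome, beyond transcript GC, but the correlation is small. Regional GC outside transcripts was not matched, clusters of related genes were not left out of the pairs, and bias of the libraries stays open.

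The third pattern concerns the microRNA genes MIR3648 and MIR663. MIR3648 fell from 44.3 FPKM (limits 31.3 to 57.3) to 7.56 FPKM (limits 3.13 to 11.99), and MIR663 from 28431 FPKM (limits 22966 to 33896) to 2934 FPKM (limits 2003 to 3866). Fewer reads from the precursor of ribosomal RNA, the product of RNA polymerase I, may explain the fall of MIR3648. This gene lies 3919 bp from a 5.8S ribosomal RNA gene in GRCh38. Its neighbour MIR3687, 191 bp away, should then be lower too, but it was listed at 0 in the control and at 697 FPKM after BMH-21, and a listed 0 can be a failed estimate, so the test decides nothing. Reads shared between repeat copies were not tested, and the position of MIR663 relative to ribosomal RNA genes was not examined.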
